A study of Mus musculus with 10 samples.

How the data were processed

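Total RNA from mouse liver was measured on 10 Agilent 2-colour oligonucleotide arrays of 22393 spots. Mice of C57/BL6 and AKR/J background were kept on 12 h light and 12 h dark, per the labels, which do not tie a strain to a genotype. RNA from several mice was pooled per condition, 500 ng was amplified and labelled, 750 ng of each cRNA was hybridised for 17 h, and the 2 RNAs of a pair were hybridised again with the dyes exchanged, per the labels. The labels put 6 arrays in DKO, 2 in RORα KO and 2 in RORγ KO.

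The deposited scanner tables hold spot intensity values, the mean pixel brightness of each spot and the median of its local background per channel, per the file headers. They were made with Agilent Feature Extraction 7.5.1 for the sets labelled as males and 6.1.1 for the mixed set, per the file headers; the labels name 1 version for all. The deposited log10 ratios, Cy5 over Cy3, came from background-subtracted signals, with a linear dye factor and LOWESS settings listed, per the file headers, and each comes with a deposited p-value from the software's error model. The authors' deposited series table holds log10 values that are the negative of these ratios spot by spot, so that its direction is Cy3 over Cy5; its column medians lay between -0.0018 and 3.06e-05. Other flags in the deposited tables mark spots as well above background, saturated or outlying.

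The raw intensities were background-corrected with normexp (offset 50) and normalised within each array by loess with limma 3.58.1 in R 4.3.3, controls and outlier spots having weight 0 in loess; outlier spots were left out of a probe's mean where other spots remained. Ratios were turned to KO over WT on the log2 scale, and spots of 1 probe were averaged. A probe was kept if the WT or KO RNA of 1 set was well above background on both arrays of that set, which 20547 of 20868 probes met. Probes were named through accessions in a RefSeq gene table of mouse assembly GRCm38.p6 (8947 probes), or by the symbol in the file where no accession matched (370 current, 624 updated and 161 kept as written); 10766 probes had no symbol. No coordinates are given because the files name no genome build. For a gene with several probes the brightest was used, which left 20393 rows, 10539 of them without a symbol. No named gene was below background or saturated on every array of its group, so no bounds are given.

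The 2 arrays of a set were averaged. The 5 sets entered 1 limma fit (lmFit and eBayes) with a mean per genotype, tested against 0 and against one another, with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual spread comes from the 3 DKO sets, so each single KO set is assumed to vary like them. Genes named in the text are Rora and Rorb, then up to 10 in each direction per genotype among those past the threshold with the same sign on every array; where fewer than 10 passed, the largest with at least 2-fold on every array were added as values. Names that are only clones, accessions or predicted genes were left out, and some genes that these rules choose are not reported here. For gene lists up to 4 members past the test are named, or the largest as a value. These rules, 31 gene lists of liver metabolism, sex-predominant genes and markers of other cell types, and most alternatives were fixed before the data were examined. List members named from the fit without the mixed set, as well as Sult2a2, Cyp2c40, Gstt1 and the unnamed transcript, were chosen after the data were seen. Lists were tested with camera, with a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over 93 pairs of list and genotype. With the preset 23 pairs passed, and with the estimated correlation 0. The test with an estimated correlation has only the residual degrees of freedom of the fit, 2 with all sets and 1 without the mixed set. Over 93 pairs it could hardly pass, and its lowest unadjusted camera p with all sets was 0.0238. Its adjusted p-values therefore cannot decide whether a list shifted.

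The fits were tested on simulated data of 20393 genes with the fitted spread. For DKO with 5 sets, 85% of 100 genes changed 2-fold and 97% of 100 genes changed 4-fold were recovered; for RORα KO 42% and 87%, and for RORγ KO 46% and 88%. Without the mixed set 97% and 100% were recovered for DKO, 97% and 100% for RORα KO, and 93% and 99% for RORγ KO. In the fit of all sets 10 unchanged genes were called for DKO, 3 for RORα KO and 4 for RORγ KO, and without the mixed set 10, 21 and 16. These simulations draw every set of a gene from 1 spread, without regard to the size of its change. In the real fit of all sets 2 genes passed for DKO, while 20 were at least 2-fold apart on all 6 DKO arrays. The recovery given for DKO with 5 sets is therefore too high for such genes. No gene passed in a single KO in either fit. At least 2-fold apart on both arrays were 24 genes in RORα KO and 14 in RORγ KO. The recovery given for the single KOs is thus too high for such genes too. A lack of calls there does not show a lack of 2-fold changes. Alternatives were the software's log ratios, the authors' table, no background correction, an offset of 10, quantile scaling of average brightness, median centring, other probe filters, all probes, single dye orientations, leaving out each DKO set, the DKO sets alone, a trended robust eBayes, a dye term with the set as a random block, and the software's error model. The software read each set on a day of its own, and the mixed set on 2, per the file headers. In the other sets day and set cannot be told apart, and the random block stands for both. It does not stand for the 2 days of the mixed set. Median signal over background ranged from 1.4 to 5.11 per channel. Correlations and overlaps under a shared WT pool were simulated 100 times. Figures were drawn with matplotlib 3.10.9.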

Results

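Liver RNA of mice lacking the nuclear receptor RORα, RORγ or both was compared with wild-type (WT) liver RNA on 2-colour oligonucleotide arrays. The RORα knockout (KO) carries the staggerer allele of Rora, an internal deletion. The double knockout (DKO) joins it with the RORγ KO. Each array held 1 KO RNA and 1 WT RNA, in Cy3 and Cy5, and each RNA was a pool of several mice, per the labels. The 10 arrays form 5 dye-swap sets of 2 arrays. A set was counted as 1 replicate, which gives 3 DKO sets (males 2, males 4 and a set labelled mixed), 1 RORα KO set (males 3) and 1 RORγ KO set (males 1). The labels do not say what was mixed, or whether the WT pools of different sets came from separate mice. The limma p-values of DKO genes therefore measure only the spread between these pools. Those of the single KOs borrow that spread, because each has 1 set. Camera p-values with the preset correlation compare list genes with other genes, so they do not measure reproducibility between pools. Between 86.6% and 99.5% of the probes were well above background in each channel, and the number of arrays limits the precision. Values are log2 ratios of KO over WT, and 20393 genes were tested, of which 9854 had a symbol.

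Rora was read first, as a check of the labels. It was lower than WT in the RORα KO set (log2 -0.91 and -0.79 on its 2 arrays), in DKO set 2 (log2 -0.96) and in DKO set 4 (log2 -1.38). It was near WT in the RORγ KO set (log2 -0.25) and in the mixed DKO set (log2 -0.12). All sets were read with the same probe, so its place on the transcript does not account for the value of the mixed set, which was kept as a DKO replicate by its label alone. No probe was named Rorb. Rora did not pass in any genotype in the limma fit of all sets, and it passed in DKO without the mixed set (adjusted p = 0.0361).

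The sex-linked transcripts did not match in the KO and WT channels of every set. Xist, the RNA of the inactive X chromosome, was 7.46-fold higher in the KO channel of DKO set 4, which is labelled as males, and 2.2-fold higher in that of the mixed set. On the arrays of DKO set 2 and of both single KO sets it lay between log2 -0.08 and 0.07. The WT channel of the mixed set had a log2 Xist brightness of 9.72, against 6.29 to 6.50 in the WT channels of the other sets. The Y-linked Eif2s3y stood at log2 -2.3 and -3.4 on the arrays of the mixed set, with a KO signal not well above background on the first of them, and at log2 0.42 and -0.35 in DKO sets 2 and 4. DKO sets 2 and 4 correlated at 0.761 across genes, while the mixed set correlated with them at 0.283 and 0.315. Genes are not independent replicates, so these correlations describe the sets only.

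**Figure D1:**
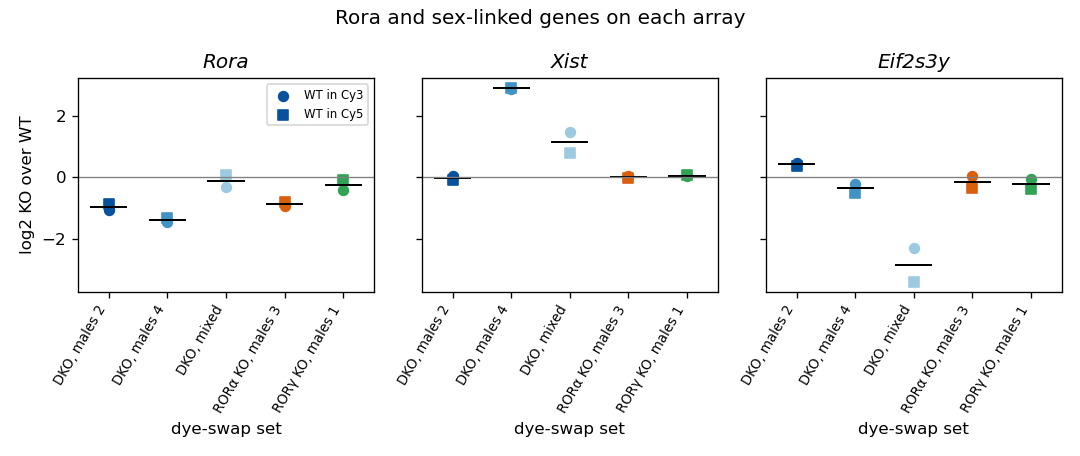
Each panel shows 1 gene; the vertical axis is log2 KO over WT, the horizontal axis lists the 5 dye-swap sets, points are single arrays (circles with WT in Cy3, squares with WT in Cy5) and bars are set means. Xist stands at 2.89 and 2.91 on the arrays of DKO set 4, and Rora stands at -0.32 and 0.08 on those of the mixed set.

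The comparison of DKO with WT asks which liver genes depend on the 2 receptors together. Hsd3b5, a male-predominant hydroxysteroid dehydrogenase of liver, fell 9.25-fold (log2 -3.21 ± 0.17, SD, n = 3 sets; adjusted p = 0.0499, limma) and was lower on 6 of 6 arrays. An unnamed transcript described as similar to glutathione S-transferase theta 1 was the other gene past the threshold; probe A_51_P377856 rose by log2 1.39 ± 0.04 (SD, n = 3), while the probe named Gstt1 stood at log2 0.09. These 2 genes, 1 higher and 1 lower, were the limma calls from all 3 sets. Both calls ended without set 2 (adjusted p = 0.099 for Hsd3b5 and 0.232), without set 4 (0.258 and 0.507), without background correction (0.254 and 0.243), without the filter on dim probes (0.05002 for both) and with trended robust variances (0.417 for both), while Hsd3b5 stayed between log2 -3.23 and -2.62 and the other between 1.33 and 1.39. The unnamed transcript also missed the threshold with the strict filter and on the arrays with WT in Cy5 alone. For Hsd3b5, offset 10 gave log2 -3.68 and the software's log ratios -3.87, so the size of its fall depends on the background correction. Without the mixed set, an alternative planned before the data were examined, the same limma fit called 2029 genes, of which 842 rose and 1187 fell.

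By size, 9 genes were at least 2-fold higher and 11 at least 2-fold lower on all 6 DKO arrays, 5 of these 20 being unnamed transcripts or clones. Apart from Hsd3b5, the genes in this paragraph did not pass in the fit of all 3 sets and are given as values; each of them passed in the limma fit without the mixed set. Sult1e1, the estrogen sulfotransferase, was 14.8-fold higher than WT (log2 3.89 ± 0.48, SD, n = 3). Igfbp1, an insulin-like growth factor binding protein, stood at log2 3.28 ± 0.91. The female-predominant cytochromes P450 Cyp2b9 and Cyp2b13 stood at log2 2.55 ± 0.79 and 2.32 ± 0.75. Cyp4a14, a fatty acid hydroxylase and PPARα target, stood at log2 2.44 ± 0.34, the fatty acid translocase Cd36 at 1.78 ± 0.23, and the ammonium transporter Rhbg at 1.28 ± 0.06. Among the lower genes, Cyp7b1, the oxysterol hydroxylase of the acidic bile acid pathway, was 7.57-fold lower (log2 -2.92 ± 0.28). Elovl3, a fatty acid elongase, was 6.48-fold lower (log2 -2.70 ± 0.61). The organic anion transporter Slco1a1 stood at log2 -2.49 ± 1.74, with -1.34, -1.64 and -4.50 in sets 2, 4 and mixed. Selenbp2 stood at log2 -1.93 ± 0.60, Hsd3b4 at -1.93 ± 0.39, the aldehyde oxidase Aox3 at -1.55 ± 0.18 and the acetyltransferase Nat8 at -1.50 ± 0.23.

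**Figure D2:**
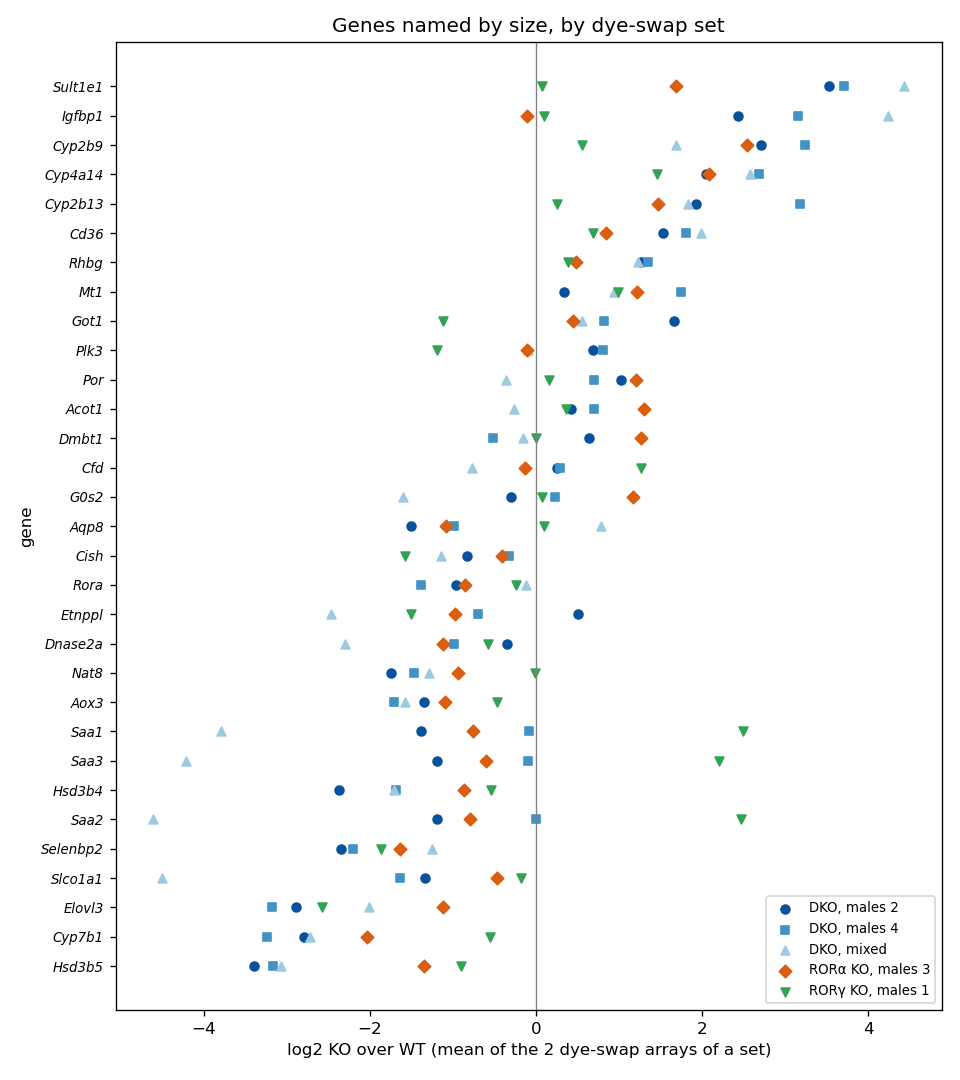
The horizontal axis is log2 KO over WT, each row is 1 gene chosen by size in 1 of the 3 comparisons, and each symbol is the mean of the 2 arrays of 1 set. Hsd3b5 lies between -3.39 and -3.07 in the 3 DKO sets, at -1.36 in the RORα KO and at -0.90 in the RORγ KO.

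Of 14 measured male-predominant liver genes, 1 passed over all genes in the fit of all 3 DKO sets, Hsd3b5, and 13 did not; adjusted over the list alone, 1 rose and 9 fell. The list median was log2 -1.22 (camera adjusted p = 1.95e-07 with the preset correlation; adjusted p = 0.779 with an estimated correlation). With an estimated correlation the test has 2 residual degrees of freedom and could hardly pass for any list. Without the mixed set 12 of the 14 fell, among them Elovl3 (log2 -3.04), Cyp7b1 (-3.02) and Selenbp2 (-2.28). Of 18 female-predominant genes none passed over all genes and 5 rose adjusted over the list alone, with a list median of log2 0.43 (camera adjusted p = 0.000322; adjusted p = 0.779 with an estimated correlation). Without the mixed set 8 of the 18 rose and 1 fell. Sult1e1 (log2 3.62), Cyp2b9 (2.98) and the cytochrome P450 Cyp3a16 (1.03) rose there, and Cyp2c40 fell (-0.44). In the mixed set Cyp3a16 was log2 -0.23. Xist differed between the channels of sets 4 and mixed, as given above. The male-predominant median was log2 -0.84 in set 2, -1.21 in set 4 and -1.47 in the mixed set, and the female-predominant median was 0.13, 0.69 and 0.22. Sult2a2, a female-predominant sulfotransferase, was log2 -0.75 in set 2, 5.42 in set 4 and 5.37 in the mixed set.

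Cytochromes P450 stood higher as a list in DKO (35 measured, median log2 0.17, camera adjusted p = 0.0256; adjusted p = 0.779 with an estimated correlation). The medians were 0.16 in set 2, 0.37 in set 4 and -0.12 in the mixed set. None of them passed over all genes, 4 rose adjusted over the list alone, and without the mixed set 12 rose and 2 fell. Sulfotransferases and sulfate donors had no list call (13 measured, camera adjusted p = 0.0797), but without the mixed set 5 rose, among them Sult1d1 (log2 1.43) and Sult1a1 (0.88), and 1 fell. Among other phase II enzymes (27 measured, camera adjusted p = 0.338), 8 rose and 3 fell without the mixed set, where the list was called higher (camera adjusted p = 0.0453; adjusted p = 0.815 with an estimated correlation). The glutathione S-transferase Gstp1 (log2 -1.11) fell there, and Mgst3 rose (0.66). Other phase I enzymes (30 measured, camera adjusted p = 0.159) counted 4 that rose, Nqo1 (log2 0.59) among them, and 4 that fell, with Ces1e at -0.58. None of these 3 lists had a member past the test in the fit of all sets; adjusted over the list alone, 3 rose and 2 fell, 5 rose and 2 fell, and 0 rose and 4 fell, in that order.

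The cholesterol synthesis list stood at a median of log2 0.73 in DKO (16 measured, camera adjusted p = 2.98e-05; adjusted p = 0.779 with an estimated correlation). None passed over all genes and 3 rose adjusted over the list alone. The medians were 0.36 in set 2, 0.17 in set 4 and 1.50 in the mixed set, and the list median without the mixed set was 0.26 (camera adjusted p = 0.000661; adjusted p = 0.815 with an estimated correlation), where 5 members rose. These include Hsd17b7 (log2 0.73) and Cyp51 (0.35), 2 enzymes of sterol synthesis. In bile acid synthesis and transport (19 measured, camera adjusted p = 0.612) 5 rose and 3 fell without the mixed set. Cyp39a1, an oxysterol hydroxylase, rose (log2 1.33), and Cyp8b1, a sterol hydroxylase of cholic acid synthesis, fell (log2 -1.24). None of these passed with all sets, and adjusted over the list alone 3 rose and 2 fell. Fatty acid oxidation genes and PPARα targets had a median of log2 0.13 (22 measured, camera adjusted p = 0.0259; adjusted p = 0.779 with an estimated correlation). None passed over all genes and 3 rose adjusted over the list alone. The medium-chain acyl-CoA dehydrogenase Acadm rose without the mixed set (log2 0.82) and Plin2, a lipid droplet protein, fell (-0.69). Transporters had a median of log2 0.12 (20 measured, camera adjusted p = 0.00572; adjusted p = 0.779 with an estimated correlation), with 4 that rose adjusted over the list alone and none over all genes, and that call ended without the mixed set (median log2 0.15, adjusted p = 0.0682).

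Core clock genes and clock outputs, several of which carry ROR response elements in their promoters, had a median of log2 -0.03 (15 measured, camera adjusted p = 0.252). Without the mixed set Arntl fell (log2 -0.30) and Usp2 rose (0.34), while Usp2 stood at -0.01 with all sets. Of the endoplasmic reticulum stress and heat shock genes (19 measured, camera adjusted p = 0.25) 6 fell without the mixed set, among them Sdf2l1 (log2 -1.13), Creld2 (-1.07) and the chaperone Hspa5 (-0.60), and the list was called lower there (median log2 -0.02, camera adjusted p = 0.0391; adjusted p = 0.815 with an estimated correlation). Kupffer cell and macrophage markers (16 measured, camera adjusted p = 0.41) counted 8 that rose without the mixed set, where the list stood higher (median log2 0.23, camera adjusted p = 0.0183; adjusted p = 0.815 with an estimated correlation). The scavenger receptor Marco was among them at log2 1.79. None of these 3 lists had a member past the test with all sets, and 2 endoplasmic reticulum stress and heat shock genes fell adjusted over the list alone. The Y-linked list stood lower (5 measured, median log2 -0.15, camera adjusted p = 0.0437; adjusted p = 0.779 with an estimated correlation), and this call ended without the mixed set (median log2 -0.07, adjusted p = 0.262).

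**Figure D3:**
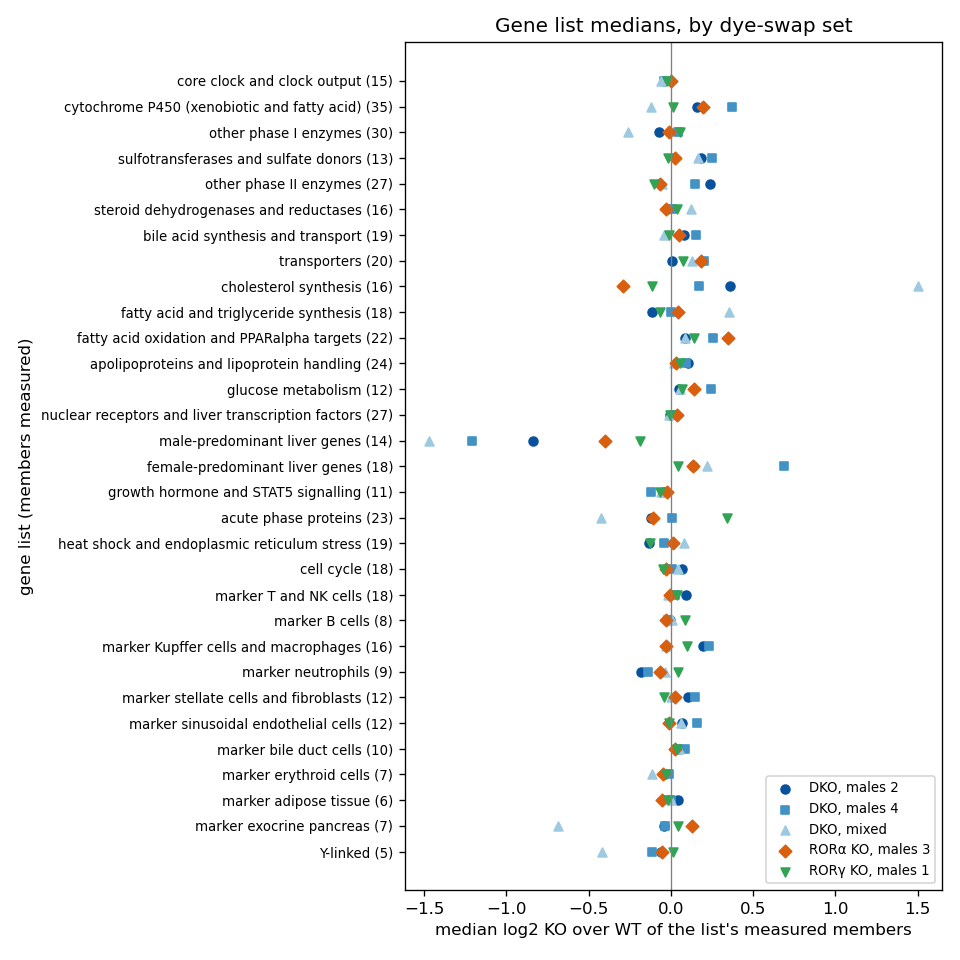
The horizontal axis is the median log2 KO over WT of a list's measured members, each row is 1 of the 31 lists fixed before the data were examined, and each symbol is 1 dye-swap set. The cholesterol synthesis list lies at 1.50 in the mixed DKO set and at -0.29 in the RORα KO, and the acute phase list at 0.34 in the RORγ KO.

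The count of DKO calls ranged from 0 to 2029 over the fits that left out 1 DKO set. With 1 residual degree of freedom, the fit without the mixed set rests on the spread between sets 2 and 4 alone.

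The RORα KO was compared with WT on 1 dye-swap set. Cyp2b9 was 5.81-fold higher (log2 2.48 and 2.60 on its 2 arrays), Cyp4a14 4.22-fold higher (1.50 and 2.66), Sult1e1 3.21-fold higher (1.57 and 1.80) and Cyp2b13 2.76-fold higher (1.33 and 1.60). The acyl-CoA thioesterase Acot1 (1.34 and 1.26), the mucin-like Dmbt1 (1.21 and 1.33), the metallothionein Mt1 (1.32 and 1.12), the P450 reductase Por (1.32 and 1.09) and the lipolysis inhibitor G0s2 (1.07 and 1.26) were also more than 2-fold higher on both arrays. Cyp7b1 was 4.11-fold lower (-1.92 and -2.16), Selenbp2 3.1-fold lower (-1.66 and -1.60) and Hsd3b5 2.56-fold lower (-1.41 and -1.30). Dnase2a (-1.12 and -1.13) and the water channel Aqp8 (-1.01 and -1.15) were lower as well. In all, 17 genes were at least 2-fold higher and 7 at least 2-fold lower on both arrays.

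Several lists stood apart in the RORα KO, each with an adjusted p of 0.779 with an estimated correlation, and with no member past the test over all genes. Fatty acid oxidation genes and PPARα targets had a median of log2 0.35 and were higher on both arrays for 17 of 22 members (camera adjusted p = 6.3e-06). Transporters had a median of log2 0.18 (camera adjusted p = 8.45e-06), with the phospholipid transporter Abcb4 at 0.88. Cytochromes P450 had a median of 0.20 (camera adjusted p = 0.00157) and glucose metabolism genes one of 0.14 (camera adjusted p = 0.021), with the glucose-6-phosphate transporter Slc37a4 at 0.80. Male-predominant genes had a median of log2 -0.40 (camera adjusted p = 2.98e-05) and were lower on both arrays for 11 of 14 members. Cholesterol synthesis genes had a median of log2 -0.29 (camera adjusted p = 0.00804), were lower on both arrays for 12 of 16 members, and were lowest for Msmo1 at -0.77. Adjusted over the list alone, 2 fatty acid oxidation genes and 1 cytochrome P450 rose, 2 male-predominant genes fell, and no transporter, glucose metabolism or cholesterol synthesis gene passed. So adjusted in the fit without the mixed set, 9 fatty acid oxidation genes rose, 13 cytochromes P450 rose and 2 fell, 9 male-predominant genes fell, 4 transporters rose, 1 cholesterol synthesis gene fell and no glucose metabolism gene passed. Female-predominant genes had a median of log2 0.13, which does not depend on the mixed set; the list was not called with all sets (camera adjusted p = 0.132) and was called without the mixed set (0.0352; adjusted p = 0.815 with an estimated correlation). Xist and Eif2s3y were log2 0.01 and -0.14 in this set.

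No gene passed in the RORα KO in the limma fit of all sets, in which the lone set is assumed to vary like the DKO sets. At an unadjusted p under 0.05 there were 676 genes, against 1020 that chance gives, and 3066 without the mixed set, where none passed either. A count under chance points to a borrowed spread too large for this set, so it does not show a lack of change. The scanner software's own error model at p under 0.01 on both arrays gave 301 genes, and a limma fit of all 10 arrays with the set as a random block gave 1. With a set correlation of 0.00101, that fit counts the dye-swap arrays of a set as nearly separate.

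The RORγ KO was also compared with WT on 1 set, whose dye-swap arrays correlated at 0.167 over all genes and at 0.387 over the brightest 25%; 45.9% of its genes had the same sign on both arrays, against 50% by chance. The acute phase serum amyloid genes were the highest, with Saa1 5.63-fold higher (log2 2.47 and 2.52), Saa2 5.56-fold higher (2.64 and 2.31) and Saa3 4.6-fold higher (2.21 and 2.19). Cyp4a14 was 2.76-fold higher (1.42 and 1.51) and Cfd, complement factor D, 2.41-fold higher (1.18 and 1.36). Elovl3 was 5.99-fold lower (-2.37 and -2.79), Selenbp2 3.65-fold lower (-1.95 and -1.78), Cish, a cytokine signalling inhibitor induced by STAT5, 2.98-fold lower (-1.66 and -1.49) and Etnppl, an ethanolamine phosphate lyase, 2.83-fold lower (-1.70 and -1.31). The kinase Plk3 (-1.35 and -1.04) and the aspartate aminotransferase Got1 (-1.04 and -1.19) were lower too. In all, 7 genes were at least 2-fold lower and 7 at least 2-fold higher on both arrays.

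The lists that stood apart in the RORγ KO had no member past the test over all genes, and each had an adjusted p of 0.779 with an estimated correlation. Acute phase proteins had a median of log2 0.34 and were higher on both arrays for 17 of 23 members (camera adjusted p = 4.01e-07). None of the 23 passed adjusted over the list alone, and 13 rose and 1 fell so adjusted without the mixed set. Fatty acid oxidation genes and PPARα targets had a median of 0.14 and were higher on both arrays for 17 of 22 members (camera adjusted p = 8.45e-06). Male-predominant genes (median log2 -0.19, camera adjusted p = 0.00157), led by Elovl3, and growth hormone and STAT5 signalling genes (median -0.06, camera adjusted p = 0.00804), led by Cish, were lower. Adjusted over the list alone, 2 genes fell in each of these last lists and no fatty acid oxidation gene passed; without the mixed set 4 male-predominant and 3 growth hormone and STAT5 signalling genes fell, and again no fatty acid oxidation gene passed. Smaller shifts were called for heat shock and endoplasmic reticulum stress genes (median log2 -0.13, camera adjusted p = 0.0305), other phase II enzymes (-0.10, 0.0313), fatty acid and triglyceride synthesis (-0.07, 0.0206), core clock genes (-0.02, 0.0498), glucose metabolism (0.07, 0.0437) and B cell markers (0.08, 0.021). The calls of core clock genes and glucose metabolism ended without the mixed set (camera adjusted p = 0.191 and 0.117), with medians that do not depend on that set. Kupffer cell and macrophage markers (median log2 0.10) were not called with all sets (camera adjusted p = 0.1585) and were called without the mixed set (0.0231; adjusted p = 0.815 with an estimated correlation).

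No gene passed in the RORγ KO in the limma fit of all sets. At an unadjusted p under 0.05 there were 314 genes, against 1020 by chance, and 1644 without the mixed set, where none passed either. Here too the count under chance points to a borrowed spread too large for the set. The scanner software's log ratios gave 2 calls, its error model gave 153 genes, and the limma fit with the set as a random block gave 0.

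The genotypes were then compared with one another, which asks what the loss of one receptor adds to that of the other. No gene differed between DKO and RORα KO, between DKO and RORγ KO, between the single KOs, or between DKO and the sum of both single KOs, in the limma fit of all sets. At an unadjusted p under 0.05 there were 524, 1286, 334 and 646 genes, against 1020 by chance, and 2627, 4845, 2092 and 3233 without the mixed set, where none passed either. The counts under chance again point to a borrowed spread too large for the single KO sets. The limma fit with the set as a random block, which counts dye-swap arrays of a set as nearly separate, called 4, 25, 0 and 0. Hsd3b5 stood at log2 -3.21 in DKO, -1.36 in RORα KO and -0.90 in RORγ KO, and Elovl3 at -2.70, -1.12 and -2.58. Cyp7b1 stood at -2.92, -2.04 and -0.55, and Sult1e1 at 3.89, 1.68 and 0.07. Igfbp1 was log2 3.28 in DKO, -0.10 in RORα KO and 0.09 in RORγ KO. Of the genes at least 2-fold higher on every array, 5 were shared by DKO and RORα KO, against 0.0075 for independent lists. These include Cyp2b9, Cyp2b13, Cyp4a14 and Sult1e1. Of the lower genes 4 were shared, against 0.00378, and these include Cyp7b1, Hsd3b5 and Selenbp2. DKO and RORγ KO shared 1 higher gene, Cyp4a14, and 2 lower genes, Elovl3 and Selenbp2, against 0.00309 and 0.00378. The single KOs shared 2 higher genes, Cyp4a14 and an unnamed transcript, and 1 lower gene, Selenbp2, against 0.00584 and 0.0024. If all sets shared 1 WT pool, unchanged groups with the fitted spread would share means of 0.72 higher and 0.68 lower genes between DKO and RORα KO (at most 3 of each in 100 simulations), and 0.58 and 0.67 between DKO and RORγ KO (at most 3 and 4), and 3.6 and 3.3 between the single KOs (at most 10 and 8). The simulation gave WT and KO RNA equal shares of the fitted variance. Against a pool shared with the mixed set stands its WT Xist brightness, log2 9.72 against 6.29 to 6.50 in the other WT channels. The simulated overlaps with DKO, which include the mixed arrays, are thus not a measure for these data. The simulated overlap of the single KOs used the spread of the DKO sets, the mixed set included, which may be too large for them. It is therefore not a measure either, and how much of any of these overlaps comes from shared WT RNA stays open.

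Across genes, the log2 ratios of DKO and RORα KO correlated at 0.475 (Spearman's rho 0.355), those of DKO and RORγ KO at -0.0392 (rho -0.208) and those of the single KOs at 0.225 (rho 0.108). If all sets shared 1 WT pool, unchanged groups with the fitted spread would correlate at 0.613, 0.615 and 0.5. The simulation assumes that WT and KO RNA hold equal shares of the fitted variance. These 3 values follow from that assumption and the number of sets, and the simulated covariances below rest on it too. The covariances were 0.0136, -0.000936 and 0.00415, against 0.0114, 0.0115 and 0.0114 simulated. Only the covariance of DKO and RORα KO exceeded the simulated value, by 0.00216. The WT Xist brightness of the mixed set, log2 9.72 against 6.29 to 6.50 in the other WT channels, argues against 1 WT pool for all sets. The labels leave open which of the other sets shared WT RNA, so these correlations are not a measure of shared effects.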

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

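The tests of Xist, Eif2s3y and Rora, and the counts under turned signs, were chosen only after the results were seen; those of dye bias, of bright genes and of neighbouring genes were not, but the bound below which neighbouring genes would argue against a donor segment was added after their count was seen.

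The following results stood out because every array of one genotype lay above WT and every array of another lay below; for single genes no difference passed in the limma fit, for lists the difference was not tested, and single KO values come from 1 set. Igfbp1 differed by log2 3.38 between DKO and RORα KO. Got1 differed by 2.13 between DKO and RORγ KO and by 1.57 between RORα KO and RORγ KO. Saa1 differed by -4.25 between DKO and RORγ KO and by -3.25 between RORα KO and RORγ KO, Saa2 by -3.27 and Saa3 by -2.80 between the single KOs. In DKO, Saa1 stood at log2 -1.38 in set 2, -0.08 in set 4 and -3.80 in the mixed set. Aqp8 and Cfd differed by -1.17 and -1.40 between RORα KO and RORγ KO. The cholesterol synthesis median differed by log2 1.02 between DKO and RORα KO and by 0.85 between DKO and RORγ KO. The acute phase and B cell marker medians differed by -0.45 and -0.11 between RORα KO and RORγ KO.

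Male-predominant genes were lower, and some female-predominant genes higher, in DKO and in RORα KO. Neither list was called with an estimated correlation (camera adjusted p = 0.779 for each), a test with too few degrees of freedom to decide. In the RORα KO the female-predominant list was not called with all sets either (camera adjusted p = 0.132). Female RNA in the KO pool could give such a pattern. In DKO set 2 and the RORα KO set, where Hsd3b5 and Cyp2b9 moved on all 4 arrays, Xist averaged log2 -0.000987, which argues against it there. In DKO sets 4 and mixed Xist was at least log2 0.80 higher on every array, so female RNA stays a candidate explanation for part of the change in those sets, for example of Sult2a2. Dye bias is argued against by the difference of the female and male list medians, which was 0.94 or more on each of the 4 arrays of DKO sets 2 and 4, while an effect of the genotype on sex-predominant genes stays open as a hypothesis.

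The mixed DKO set was unlike the male DKO sets. Unequal sex of its RNAs is a candidate explanation, since Eif2s3y stood at log2 -2.85, with a KO signal not well above background on 1 of the 2 arrays. The other measured Y-linked genes changed less there, with Uty at -0.43, Kdm5d at -0.42, Zfy2 at -0.13 and Zfy1 at -0.06. Uty was near background, with no WT array of males 1, 2 and 3 well above it, so it could fall little. Kdm5d, Zfy2 and Zfy1 were well above background in both channels of the mixed set. KO RNA not from staggerer mice cannot be told apart, since Rora stood at log2 -0.12, above all 3 other staggerer sets (mean -1.07, SD 0.28). The upper limit of their 95% prediction interval was 0.33, which lies above equal Rora in KO and WT. A value under that limit therefore says nothing about the source of the RNA, and 3 sets are too few to place it. Noise of dim spots stays open, since its dye-swap arrays correlated at 0.0288 over all genes and at 0.321 over the brightest 25%, between the values set in advance for and against it. The older software version of this set is confounded with it.

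Genes next to a targeted locus may differ because they came from the donor strain of the mutation. Of the measured genes among the 50 on each side of Rora (42), in the gene order of assembly GRCm38.p6, 0% were among the 2% with the largest change in the RORα KO (one-sided Fisher's exact p = 1). This number of genes is too small to exclude a share above or below 2%, so a donor-strain segment around Rora cannot be told apart from none. The labels name C57/BL6 and AKR/J without tying either to a genotype, and strain differences elsewhere in the genome were not tested.

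With 3 DKO sets there are 4 sign patterns, too few for a share under 0.05; the real one gave 2 genes and the highest other 0, so that only 1 pattern gave as many. Without the mixed set there are 2 patterns, again too few, with 2029 genes in the real one and 0 in the other, so again 1 gave as many.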

How the results depend on the processing

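The fits that leave out the mixed set together with a second change, the single DKO sets, and the trended robust fit of the between-genotype counts were chosen only after the results were seen, as was the rule for when a correlation had turned; the other alternatives were planned.

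The count of DKO genes depended on the mixed set, on the handling of the signals and on the variance model, and the cause was not tested. With all sets it was 2; it was 10 with the software's log ratios or the authors' table, 0 without background correction, without the filter on dim probes or with trended robust variances, 9 with offset 10, 20 with median centring, 1 with the strict filter, 13 and 1 on the arrays with WT in Cy3 or Cy5 alone, 78 by the software's error model and 1387 in the fit of 10 arrays with a dye term and the set as a random block. The error model asked for p under 0.01 on all 6 DKO arrays, but on only 2 arrays for each single KO. Its counts cannot be compared between DKO and the single KOs. Leaving out 1 replicate gave 0 to 2029. Among fits of the male sets it was 40 with the software's log ratios, 902 without background correction, 3083 with offset 10, 3423 with median centring, 2056 without the filter, 1747 with the strict filter, 2226 with all probes, 5428 with trended robust variances and 7600 in a fit of 8 arrays with the set as a random block. Both fits with the set as a random block count dye-swap arrays of 1 RNA pair as separate. The set correlation was 0.00101 for 10 arrays and -0.29 for 8. Of the 2029 genes, 866 were among the 1387, 1824 among the 5428 and 2025 among the 7600. Genes at least 2-fold apart numbered 20 on all 6 arrays and 70, 75 and 148 in sets 2, 4 and mixed alone.

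For the RORα KO, 0 genes became 301 by the error model and 1 in the 10-array fit, and with the male sets 3 with offset 10, 148 with median centring, 130 with trended robust variances and 2561 in the 8-array fit. For the RORγ KO, 0 became 153 by the error model and 2 with the software's log ratios, the authors' table or WT in Cy3 alone, and with the male sets 7 with the software's log ratios, 15 with offset 10, 69 with median centring, 148 with trended robust variances and 540 in the 8-array fit. DKO against RORα KO gave 4 in the 10-array fit, and with the male sets 71 with median centring, 513 with trended robust variances and 1794 in the 8-array fit. DKO against RORγ KO gave 1 with WT in Cy3 alone and 25 in the 10-array fit, and with the male sets 27 with offset 10, 1455 with median centring, 1844 with trended robust variances and 5224 in the 8-array fit. The single KOs against each other gave 48, 49 and 808 with the male sets by median centring, trended robust variances and the 8-array fit, and the sum of both single KOs against DKO gave 105, 964 and 2647. The cause was not tested.

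Leaving out 1 replicate, Rora in DKO ranged from log2 -1.17 to -0.54. The lowest value came without the mixed set, and Rora passed the threshold there, in the 8-array fit and, at -0.82, in the 10-array fit. With trended robust variances and the male sets Rora also passed. In the 8-array fit Rora passed in the RORα KO (-0.85). Its value in the RORα KO was log2 -1.21 with offset 10, -1.38 with the software's log ratios and -0.78 without background correction. Cfd (log2 0.27, without the mixed set and in the 8-array fit) and Usp2 (log2 0.34, also with trended robust variances) turned from lower to higher in DKO, where their values with all sets had not passed. Leaving out 1 replicate, they ranged from -0.26 to 0.27 and from -0.21 to 0.34; the cause was not tested. The lists called numbered 23, and 11 without background correction. The correlation of DKO and RORγ KO was 0.135 and 0.095 with WT in Cy3 or Cy5 alone, and 0.0173 without replicate 2; that of the single KOs was 0.348 in either orientation.

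Of the other values, 2507 of single genes and 1150 of lists kept direction and side of the threshold, 365 and 37 passed only under the alternative, 5 and 51 no longer passed, and 28 and 64 that passed in neither fit changed sign. Quantile scaling of brightness leaves ratios unchanged by construction. A fit by day was not run, because each set has days of its own. No paired analysis was possible because the genotypes share no replicate numbers. Signal over background, lowest on the mixed arrays at 1.4, limits what dim spots can show.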

Other observations

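The members named in this part did not pass in the limma fit of all sets and passed in that without the mixed set, and their naming from that fit was chosen only after the results were seen. Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, rose in DKO (log2 1.14; adjusted p = 0.0326, limma) and stood at 1.25, 1.03 and 0.13 in sets 2, 4 and mixed. Of 12 glucose metabolism genes 2 rose in that fit. Among 27 nuclear receptors and liver transcription factors 2 rose and 1 fell there. The aryl hydrocarbon receptor Ahr (log2 0.65) and the constitutive androstane receptor Nr1i3 (0.57) rose, and the transcription factor Onecut1 fell (-0.45). Among apolipoproteins and lipoprotein handling genes (24 measured) 5 rose and 3 fell there. Apoa4 (log2 0.87) and the HDL receptor Scarb1 (0.43) rose, and the fatty acid binding protein Fabp2 fell (-0.38).

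Markers of bile duct cells (10 measured) counted 3 that rose in DKO without the mixed set. Krt18 and Krt8, which hepatocytes also express, stood there at log2 0.48 and 0.49. Of the marker lists of T and NK cells, B cells, neutrophils, stellate cells, sinusoidal endothelium, erythroid cells, adipose tissue and exocrine pancreas, none was called in DKO with all sets, with medians of log2 0.03, 0.02, -0.15, 0.15, 0.07, -0.06, -0.07 and -0.26. The stellate cell markers were called higher without the mixed set (median log2 0.09, camera adjusted p = 0.0222) and the neutrophil markers lower (median -0.17, camera adjusted p = 0.0453), each with an adjusted p of 0.815 with an estimated correlation; the other 6 lists were not called there either. Steroid dehydrogenases (16 measured, median 0.03, mean -0.26), growth hormone signalling (median -0.07), acute phase proteins (-0.26), cell cycle genes (0.04) and fatty acid synthesis (0.19) were not called in DKO either.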
